A study of Mus musculus with 15 samples.

How the data were processed

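Gene expression was measured in mouse lung on 15 one-colour Affymetrix arrays. Per the labels, 8 arrays held RNA from normal lung cells and 7 held RNA from advanced lung adenocarcinomas of knock-in mice carrying an inducible oncogene. Tumours were dissected by hand about 10 months after infection with an adenovirus carrying Cre recombinase. RNA was isolated with a small-sample kit (PicoPure), amplified and labelled with the WT-Ovation One-Direct system and marked with biotin, per the labels' protocols. The labels give the same protocols for both groups and name no array batch or date. Each sample is called a biological replicate in the labels; which animal it came from is not given in the sources used here.

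The authors deposited 1 table of log2 expression values, with 45101 probe sets in rows and the 15 arrays in columns. RMA and the affy package are named in the submitters' processing notes, without versions. RMA corrects background, normalizes between arrays and summarises the probes of each probe set, so the deposited log2 values carry no detection call and no raw intensity; the genome build is not given in the sources used here. Each column was matched to its sample by name, no 2 arrays held identical values, and the number of arrays limits the precision.

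Gene names came from the platform annotation: 34958 probe sets named 1 gene, 932 named several and 9211 named none. Of the named probe sets, 99.4% had an Entrez identifier found in the RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols and was used for names only. Probe sets naming several genes were left out of the gene tests. Of probe sets that named the same gene, the one with the highest mean over all 15 arrays stood for the gene, which left 18194 genes; 9012 of them had more than 1 probe set. Some genes of the model and the field are not analysed here.

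Tumours were compared with normal lung in R 4.3.3 with limma 3.58.1 (lmFit and eBayes), without filter or covariate, two-sided, with Benjamini-Hochberg adjustment over all 18194 genes. A gene was called changed at an adjusted p under 0.05 and counted again at a change of at least 2-fold. The SE beside a log2 difference is limma's moderated SE. Gene lists fixed beforehand, 27 in number with 496 genes of which 454 were measured, were tested against all other genes with limma's camera at a preset correlation of 0.01, and again with the correlation estimated for each list. Members were counted as risen or fallen over all genes and adjusted over the list alone. The lists covered markers of alveolar type 2, alveolar type 1, club, ciliated, endothelial, fibroblast, smooth muscle, cardiac, mesothelial, macrophage, neutrophil, T and NK, B and plasma, antigen-presenting and red blood cells, and genes of the cell cycle, MAPK output, RAS, Notch, progression, gastric endoderm, glycolysis, lipid synthesis, p53, NRF2, interferon and immediate early responses. Each list's median change was also set against 10000 random lists whose genes lay within 100 ranks of its members in mean tumour level, and against as many random lists matched in the same way on the mean over all arrays. Both comparisons, the ribosomal set and the classes of genes by level were chosen after the data were seen. Matching on the tumour level takes part of a real rise as its reference, and both treat genes as independent.

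The spread within a group was, for each array, the mean over genes of the squared deviation from the mean of the group's other arrays, multiplied by (n - 1)/n so that the sizes of the groups do not matter; that factor was added after the test on simulated data showed the need for it. Its difference between groups, and that of each array measure, was tested over all 6435 splits of the 15 arrays (exact permutation test, two-sided). The deviations were computed once within the real groups and not again for each split, and those of a group depend on one another. For the spread the p-value is therefore approximate. Control probe sets of the array were averaged as hybridization controls (bacterial transcripts added to the labelled sample), poly-A Dap controls (bacterial RNA added to the sample before labelling) and mouse Actb and Gapdh controls.

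Genes named in the text follow a rule. It takes the 12 largest rises and 12 largest falls among called genes whose tumour and normal arrays did not overlap and whose brighter group lay at or above the median of the table (6.37); 4 unnamed transcripts among the falls were passed over. It adds from each list up to 3 risen and 3 fallen members of smallest adjusted p, genes of the model and the field, and Xist with Y-linked genes. Together these were 154 genes.

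The tests were tried on simulated arrays with the spread of the real ones. With 100 genes shifted by 1 and 100 by 2 on the log2 scale, the comparison of tumour with normal recovered 38% and 82% of them, with 6 false calls among 18194 genes. A list shifted by 1 was called and 0 of the other 26 lists were. The simulated genes were drawn independently of one another. This count therefore cannot show how often lists of correlated genes would be called falsely. Alternatives were a filter on dim genes (lowest 40% of gene means), the mean of a gene's probe sets, every probe set, renormalization (quantile, median, median and SD), each array left out, array weights, a trended robust prior, a replicate block, covariates for Y-linked expression and for the 3-prime minus 5-prime difference of the Actb and Gapdh controls, an exact Wilcoxon test, other thresholds, camera on ranks and the 1000 brightest genes. The design and most alternatives were fixed before the data were examined. Scaling to the same SD, leaving out normal replicates 2 and 8 or tumour replicates 5 and 6, the spread without its factor and both kinds of matched lists were added afterwards. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.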

Results

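The data described RNA levels in advanced lung adenocarcinomas driven by a knock-in oncogene and in normal lung. There were 8 normal lung arrays and 7 tumour arrays, with 18194 genes measured as RMA log2 values. The labels call the samples biological replicates, and p-values refer to the spread between these arrays. The question that the design implies is which genes distinguish advanced tumours from normal lung.

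The 2 groups differed in signal before any gene was considered. Control probe sets for the housekeeping genes Actb and Gapdh averaged 9.09 ± 1.22 (SD, n = 8) on normal arrays and 13.33 ± 0.09 (SD, n = 7) on tumour arrays, a difference of 4.24 on the log2 scale (exact permutation p = 0.000311, two-sided, adjusted p = 0.000435 over 7 array measures). Hybridization controls ran the other way, at 14.07 ± 0.28 on normal and 10.60 ± 0.07 on tumour arrays. The poly-A Dap controls lay at 4.88 ± 0.47 and 8.21 ± 0.57. For both of these the exact permutation p was 0.000155, the smallest that the 6435 splits can give. Values within an array had an SD of 1.50 ± 0.18 on normal and 2.20 ± 0.01 on tumour arrays (exact permutation p = 0.000155). The 3-prime minus 5-prime difference of the Actb and Gapdh controls was 0.98 ± 0.62 on normal and 0.40 ± 0.07 on tumour arrays (exact permutation p = 0.0329). Every tumour array lay below every normal array in the hybridization controls and above every one in the Dap and the Actb and Gapdh controls, so array signal and tissue cannot be told apart.

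**Figure D1:**
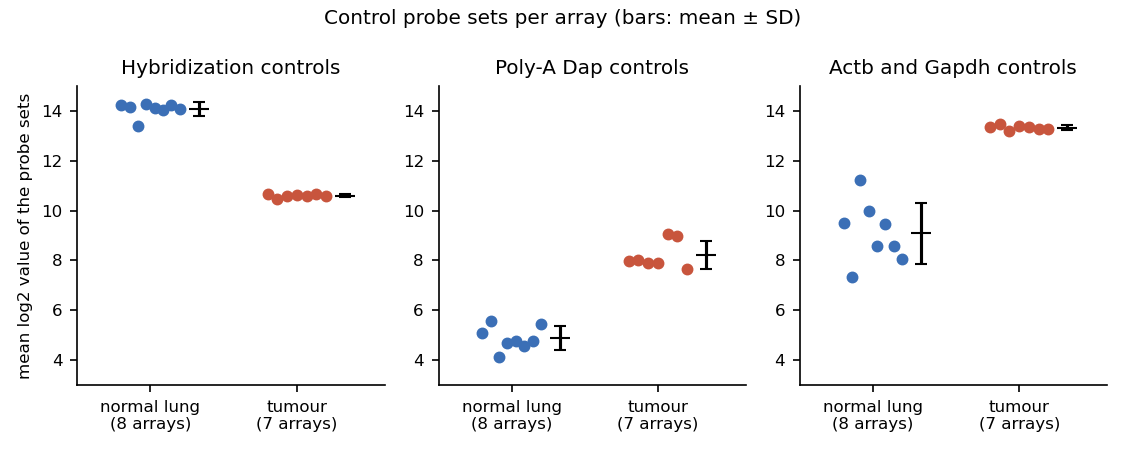
Mean log2 value of 3 sets of control probe sets on each array (points) for 8 normal lung and 7 tumour arrays, with the group mean and SD (bars). Hybridization controls averaged 14.07 on normal and 10.60 on tumour arrays, and Actb and Gapdh controls 9.09 and 13.33.

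Rplp2, Lcn2 and Scgb1a1 were the largest rises, and Synpo2l and Myod1 the largest falls, among changed genes whose tumour and normal arrays did not overlap and whose brighter group lay at or above the table's median. Rplp2, a ribosomal stalk protein gene, rose by 7.97 ± 0.51 on the log2 scale (SE; limma adjusted p = 8.13e-10), from 6.07 ± 1.51 (SD, n = 8) to 14.04 ± 0.07 (SD, n = 7). Lcn2, which encodes the iron-carrier-binding protein lipocalin 2, rose by 7.54 ± 0.41 (limma adjusted p = 1.39e-10), and Scgb1a1, the main secretoglobin of club cells, by 7.36 ± 0.54 (limma adjusted p = 4.22e-09). Scgb1a1 lay at 5.54 ± 0.75 on the normal lung arrays, below the table's median of 6.37. The other largest rises were Atp5b (6.45), the surfactant-processing protease gene Napsa (6.45), Cd9 (6.39), Cyp2f2 (6.36), Rplp0 (6.26), P4hb (6.26), Gkn2 (6.24), Rpl22l1 (6.20) and Pik3cd (6.18). Synpo2l, a gene of striated muscle, fell by 8.07 ± 0.42 (SE; limma adjusted p = 7.08e-11), and Myod1, a transcription factor of skeletal muscle, fell by 6.78 ± 0.82 from 10.44 ± 2.49 on normal lung arrays. The other largest falls were Opa3 (-6.60), Serpina7 (-6.52), the keratin gene Krt13 (-6.17), Defb1 (-5.90), Paqr5 (-5.84), Pramel34 (-5.83), Cntnap2 (-5.55), Lipt1 (-5.55), Prr5 (-5.36) and Peli1 (-5.32). Pik3cd and Lipt1 each had 1 further probe set called the opposite way, Opa3 had 3 and Peli1 had 2. Among normal arrays Myod1 was lowest on replicate 3 (4.92) and highest on replicate 2 (12.17). The Actb and Gapdh controls were brightest (11.24) on the former and weakest (7.33) on the latter. Synpo2l, Serpina7, Krt13 and Defb1 were lowest and highest on the same arrays. Opa3, Paqr5, Prr5 and Peli1 were also lowest on replicate 3, Cntnap2 was highest there, and Pramel34 and Lipt1 were neither. Whether array signal accounts for these falls was not tested.

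In all, 13292 of 18194 genes changed (73.1%; limma, adjusted p under 0.05), 7201 higher and 6091 lower in tumours. The balance depended on the processing, with 6599 higher and 1473 lower when dim genes were left out, 5947 higher and 3963 lower with arrays scaled to the same SD, and 14139 higher and 17809 lower when every probe set was tested. At least 2-fold changes numbered 10309, with 6237 higher and 4072 lower. Tumour and normal arrays did not overlap for 7618 genes (41.9%), where chance gives 0.0311%. Among 41 ribosomal protein genes 37 rose and 2 fell, with a median difference of 2.92, and of 1.35 to 3.10 after the 3 renormalizations tried. Random lists of the same tumour level had a median of 2.82, and the ribosomal median lay at their percentile 62.0, whereas random lists of the same mean over all arrays had a median of 1.37 and none of the 10000 reached it. The median of all genes was 0.13, and -0.01 to 0.30 after those renormalizations. How direction went with brightness depended on the arrays by which brightness was measured. Of 10 equal classes of genes by tumour level, which is itself part of the difference, the brightest held 1602 risen and 13 fallen genes and the dimmest 0 and 1644. In classes by normal level, also part of the difference, these were 739 and 418 in the brightest and 246 and 1017 in the dimmest. By the mean of both groups they were 1302 and 76, and 8 and 1450, although the wider spread of values on tumour arrays enters that mean. Of 6494 changed genes with several probe sets, 1995 had another one called in the opposite direction. Which strand and region of the RNA the labelled material of each group represented is not given in the sources used here, and a difference between the groups in them would enter every value, the largest falls included. Arrays given the same distribution called 9505 genes, of which 8396 were among the 13292 with the same direction, and 744 of the 13292 had the opposite sign.

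**Figure D2:**
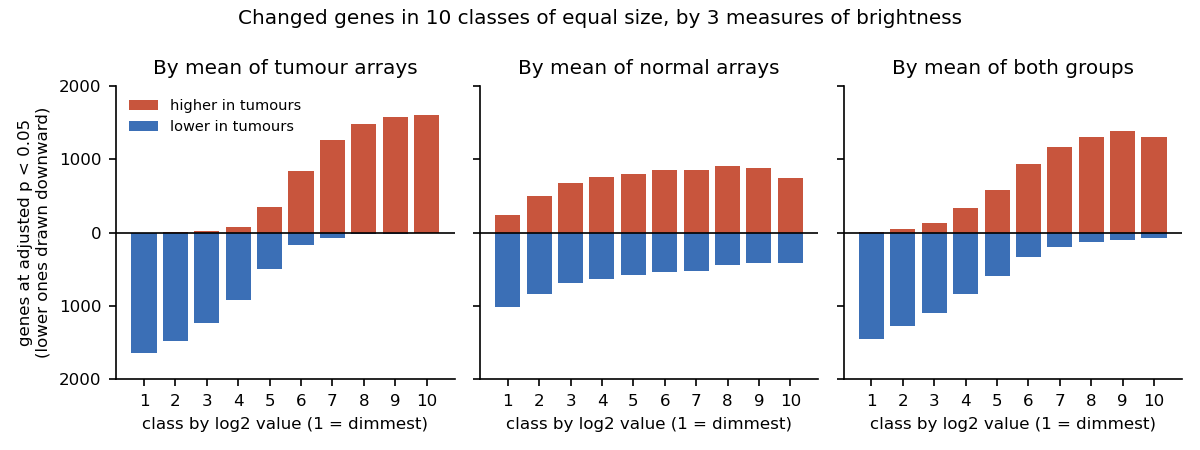
Number of genes called higher (upward bars) or lower (downward bars) in tumours at a limma adjusted p under 0.05, in 10 classes of genes of equal size ordered by mean log2 value on the 7 tumour arrays (left), on the 8 normal arrays (middle) or over both group means (right). The brightest class held 1602 higher and 13 lower genes by tumour level, 739 and 418 by normal level, and 1302 and 76 by the mean of both groups.

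Of 19 measured markers of alveolar type 2 cells, the surfactant-making cells of the alveolus, 17 rose and 0 fell, and 17 rose when adjusted over the list alone. The list's median difference was 3.01 (camera adjusted p = 0.000778), a call that was lost with an estimated correlation (adjusted p = 0.454), with dim genes left out (adjusted p = 0.0615) and with arrays scaled to the same SD (adjusted p = 0.0678). Napsa rose by 6.45 ± 0.26 (SE; limma adjusted p = 6.12e-12), the membrane mucin gene Muc1 by 4.58 ± 0.22 and the lipid transporter gene Abca3 by 4.36 ± 0.48. The list's median lay at percentile 52.5 of random lists of the same tumour level and at percentile 99.98 of random lists of the same mean over all arrays (adjusted p = 0.0162 over the 27 lists). Sftpc, surfactant protein C, rose by 3.10 ± 0.52 (limma adjusted p = 4.44e-05) on its brighter probe set, while its other probe set was called the opposite way. The brighter set had the identical value of 15.11 on 4 of 7 tumour arrays and was the brightest of all probe sets on 6 of the 7. At this top of the scale a higher level may not have been measurable, so the rise of 3.10 may be a lower bound. Tied values occurred in 3830 genes, and no raw intensity was available to test for such a limit. The call of Sftpc was lost with arrays scaled to the same SD (0.65, limma adjusted p = 0.280). With the mean of both probe sets the difference was -2.30 (limma adjusted p = 0.00222). Nkx2-1, the lineage factor of lung epithelium, differed by -0.07 ± 0.21 (adjusted p = 0.767), and after quantile renormalization by -0.75 (adjusted p = 0.00802).

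**Figure D3:**
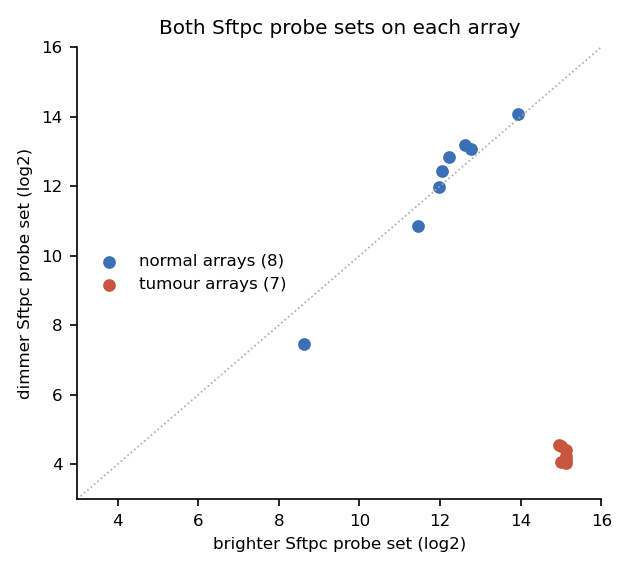
Log2 value of the 2 Sftpc probe sets on each of 8 normal (blue) and 7 tumour (red) arrays, with the line of equality dotted. On tumour arrays the brighter set, at the top of the scale, averaged 15.06 and the dimmer 4.28, and on normal arrays they averaged 11.96 and 11.99.

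Club cell markers rose in 8 of 14 members and fell in 2, with the same counts adjusted over the list alone. Besides Scgb1a1, the cytochrome gene Cyp2f2 rose by 6.36 ± 0.61 and haptoglobin (Hp) by 4.47 ± 0.46, whereas Upk3a (-1.61 ± 0.19) and Krt15 (-1.44 ± 0.21) fell. The list was not called (median 2.18, camera adjusted p = 0.208). Alveolar type 1 markers split, with 6 of 16 higher and 4 lower, also when adjusted over the list alone (median 0.67, camera adjusted p = 0.847). The water channel gene Aqp5 rose by 2.93 ± 0.51, Ager by 2.61 ± 0.63 and Emp2 by 2.22 ± 0.47. Rtkn2 (-1.95 ± 0.53), the basement membrane collagen gene Col4a3 (-1.46 ± 0.54) and Spock2 (-1.07 ± 0.43) fell. With arrays scaled to the same SD the calls of Ager and Emp2 were lost (adjusted p = 0.394 and 0.225). The call of Col4a3 ended without tumour replicate 1, and that of Spock2 when any 1 of 8 arrays was left out (normal 1, 3, 5 or 6 or tumour 1, 2, 4 or 7), with an adjusted p of at most 0.0545 and 0.0658. Ciliated cell markers did not move as a list (median 0.19, mean -0.08, camera direction down with adjusted p = 0.780). Of 18 members the cilium gene Cfap126 rose by 1.05 ± 0.45, and the axonemal dynein genes Dnaic1 (-5.00 ± 0.61) and Dnah5 (-0.87 ± 0.33) and the gene Tekt1 (-1.10 ± 0.43) fell. Adjusted over the list alone, 0 rose and 1 fell. The calls of Cfap126 (without normal 1, 2, 5, 6 or 7 or tumour 5 or 6), Dnah5 (without normal 4 or tumour 1, 3, 4 or 7) and Tekt1 (without normal 1 or 6 or tumour 1, 2, 3, 4 or 7) each ended when 1 array was left out, with an adjusted p of at most 0.116, 0.0555 and 0.0622. Ciliated markers averaged 8.12 and 7.38 on tumour replicates 5 and 6, and between 5.40 and 5.81 on the other tumours. Club cell markers averaged 11.16 and 10.60 on those 2 tumours and 8.33 to 9.27 on the others.

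**Figure D4:**
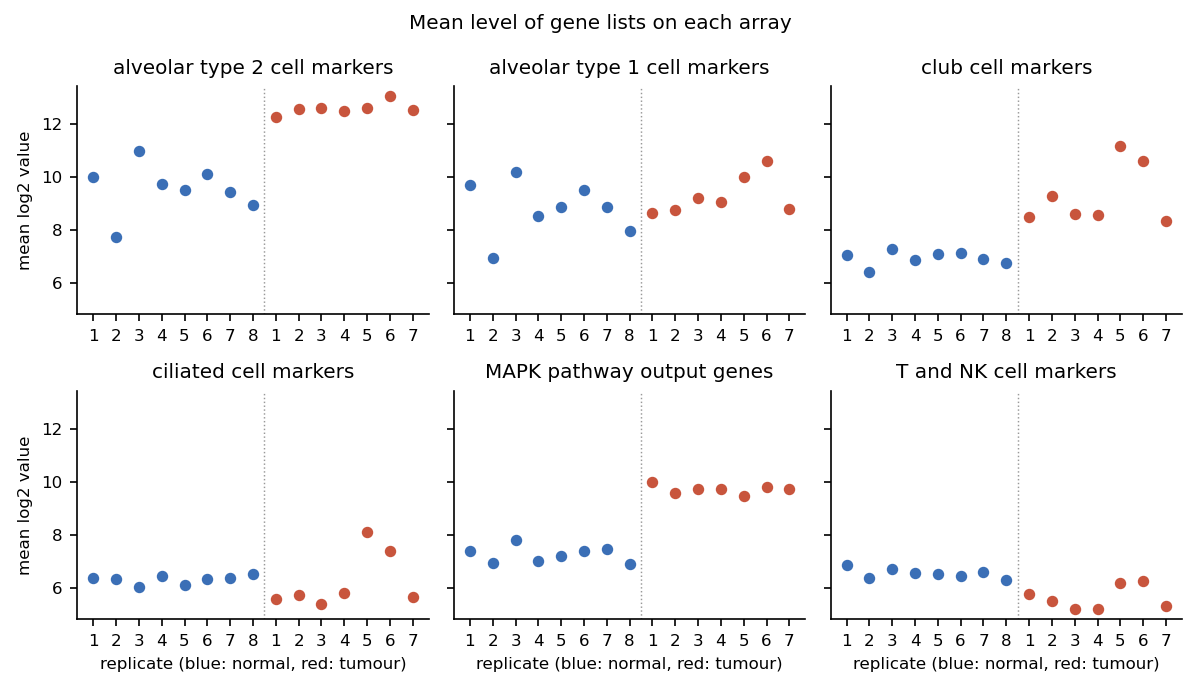
Mean log2 value of 6 gene lists on each of 8 normal (blue) and 7 tumour (red) arrays, by replicate number. Ciliated cell markers averaged 8.12 and 7.38 on tumour replicates 5 and 6, and MAPK output genes lay above every normal array on all 7 tumour arrays.

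Of 18 measured genes that report the output of the RAS-MAPK cascade, 16 rose and 0 fell in the oncogene-driven tumours, and 16 rose when adjusted over the list alone. The list's median difference was 2.70 (camera adjusted p = 0.000778), a call that was lost with an estimated correlation (adjusted p = 0.108) and with dim genes left out (adjusted p = 0.0615). Phlda1 rose by 5.10 ± 0.26 (SE; limma adjusted p = 6.63e-11), from 6.52 ± 0.62 (SD, n = 8) to 11.62 ± 0.29 (SD, n = 7). The receptor gene Epha2 rose by 3.29 ± 0.27, the ERK phosphatase gene Dusp4 by 2.92 ± 0.26 and cyclin D1 (Ccnd1) by 2.79 ± 0.38. The list's median lay at percentile 98.0 of random lists of the same tumour level (adjusted p = 0.147 over the 27 lists) and at percentile 99.8 of random lists of the same mean over all arrays (adjusted p = 0.0450). Of 17 RAS pathway components 13 rose and 2 fell, also when adjusted over the list alone. Akt1 rose by 3.48 ± 0.26, Map2k2 by 2.91 ± 0.26 and Map2k1 by 2.29 ± 0.19, while the RAS inhibitor gene Nf1 (-0.96 ± 0.23) and Egfr (-0.53 ± 0.22, limma adjusted p = 0.0390) fell. Akt1 had 1 further probe set called the opposite way, and the call of Egfr ended when any 1 of 9 arrays was left out (normal 1, 3, 4 or 8 or tumour 1, 3, 4, 5 or 6; adjusted p at most 0.0741). The list's median was 1.21 (camera adjusted p = 0.0280; adjusted p = 0.441 with an estimated correlation).

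Immediate early and heat shock genes rose in 11 of 18 members and fell in 0, also when adjusted over the list alone. Ier2 rose by 4.80 ± 0.26, the AP-1 gene Junb by 3.71 ± 0.30 and the antiproliferative gene Btg2 by 3.36 ± 0.28. Their median was 1.03 (camera adjusted p = 0.0486; adjusted p = 0.580 with an estimated correlation). That call ended when any 1 of 8 arrays was left out (normal 2, 4, 5, 6 or 8 or tumour 1, 5 or 6; adjusted p at most 0.0886), and after quantile renormalization the median was -0.08. p53 target genes rose in 11 of 18 and fell in 1, also when adjusted over the list alone. Btg2 was among them, with the adhesion gene Perp (3.88 ± 0.41) and the polymerase gene Polk (2.17 ± 0.22), and Eda2r fell by 0.83 ± 0.27. Their median was 1.33 (camera adjusted p = 0.0455; adjusted p = 0.441 with an estimated correlation), and the call ended without normal replicate 5 or 8 or tumour replicate 5 or 6 (adjusted p at most 0.0577). Among other genes of the model, the cell cycle kinase gene Cdk4 rose by 4.70 ± 0.38 (limma adjusted p = 1.08e-08) and Myc by 2.06 ± 0.37. Cdkn2a, the Ink4a and Arf tumour suppressor locus, fell by 0.91 ± 0.31 and the chromatin gene Hmga2 by 1.24 ± 0.37. The collagen receptor gene Ddr1 differed by 1.35 ± 0.66 without passing the test (limma adjusted p = 0.0713), but it passed without normal replicate 1 (1.62, adjusted p = 0.0334) or 6 (1.66, adjusted p = 0.0269). It also passed with the 3-prime minus 5-prime covariate (2.72, adjusted p = 0.000366) and with arrays centred on their medians (1.53, adjusted p = 0.0498). These were 4 of 28 other settings, and in the rest the limma adjusted p reached 0.679. With 1 array left out the difference was as low as 0.88 and the limma adjusted p at most 0.138.

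Notch pathway genes rose in 10 of 23 members and fell in 5, also when adjusted over the list alone, and were not called as a list (median 0.39, camera adjusted p = 0.733). Notch1 rose by 1.94 ± 0.28 (limma adjusted p = 9.15e-06), a call lost after quantile renormalization (0.62, adjusted p = 0.127). Its target Hes1 rose by 2.96 ± 0.24 and the gamma-secretase subunit gene Psenen by 3.75 ± 0.24. The coactivator gene Maml2 (-1.71 ± 0.24), Hes5 (-1.55 ± 0.30) and Hey2 (-1.36 ± 0.31) fell. Maml2 (means 5.99 and 4.28 on normal and tumour arrays) and Hey2 (5.08 and 3.72) lay below the table's median of 6.37 in both groups. Hes5 went from 7.86 to 6.30. Most genes this dim on tumour arrays were called lower, so these falls say little about the pathway.

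Glycolysis genes were higher in tumours in 13 of 14 measured members, with 1 lower, also when adjusted over the list alone. The list as written includes Gapdh, whose control probe sets were part of the measure of array signal. Tpi1 rose by 5.28 ± 0.42, lactate dehydrogenase A (Ldha) by 4.83 ± 0.37 and Aldoa by 4.56 ± 0.29, and the lactate transporter gene Slc16a3 fell by 0.73 ± 0.25, a call lost after quantile renormalization (-0.11, adjusted p = 0.799). The median was 2.21 (camera adjusted p = 0.00116; adjusted p = 0.441 with an estimated correlation), at percentile 40.9 of random lists of the same tumour level and at percentile 94.6 of those of the same mean over all arrays (adjusted p = 0.290 over the 27 lists). Targets of NRF2, the regulator of antioxidant genes, rose in 15 of 18 members and fell in 0, also when adjusted over the list alone. The glutathione transferase gene Gsta4 rose by 5.00 ± 0.46, Cbr3 by 4.61 ± 0.32 and Taldo1 by 3.48 ± 0.24. Their median was 2.13 (camera adjusted p = 0.00116; adjusted p = 0.441 with an estimated correlation), at percentiles 65.1 and 96.8 of these 2 kinds of random lists (adjusted p = 0.215 for the latter). Fatty acid and sterol synthesis genes rose in 11 of 21 and fell in 2, also when adjusted over the list alone, without a call for the list (median 1.02, camera adjusted p = 0.101). The list was called without normal replicate 3 (adjusted p = 0.0478), with the 3-prime minus 5-prime covariate (median 1.54, adjusted p = 0.0263) and with the mean of a gene's probe sets (median 0.98, adjusted p = 0.0499). The lipogenic regulator Srebf1 rose by 5.13 ± 0.28, Me1 by 4.19 ± 0.33 and fatty acid synthase (Fasn) by 3.27 ± 0.31, and Elovl6 (-1.72 ± 0.27) and Mvk (-0.45 ± 0.17) fell. The call of Mvk ended without tumour replicate 1 (adjusted p = 0.0581).

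Immune markers went in different directions. Macrophage markers rose in 13 of 20 members and fell in 1, also when adjusted over the list alone. The complement genes C1qa and C1qc rose by 3.61 ± 0.29 and 2.84 ± 0.34 and the lysosomal gene Cd68 by 2.62 ± 0.24, and Cd5l fell by 1.30 ± 0.25. Their median was 1.57 (camera adjusted p = 0.0280; adjusted p = 0.580 with an estimated correlation), and the call was lost without tumour replicates 5 and 6 (adjusted p = 0.0678) or normal replicates 2 and 8 (adjusted p = 0.0553). T and NK cell markers fell in 11 of 17 members and rose in 0, also when adjusted over the list alone. Cd247, a T cell receptor chain gene, fell by 2.20 ± 0.43, Cd8b1 by 1.71 ± 0.28 and the NK receptor gene Ncr1 by 1.34 ± 0.24, all to means between 4.43 and 5.06, below the table's median. Their median was -0.91 (camera adjusted p = 0.0136; adjusted p = 0.454 with an estimated correlation), at percentile 22.7 of random lists of the same tumour level and at percentile 11.2 of those of the same mean over all arrays. Antigen presentation genes rose in 10 of 16 and fell in 2, also when adjusted over the list alone (median 1.21, camera adjusted p = 0.133). The class II genes H2-DMa, Cd74 and H2-Ab1 rose by 4.67 ± 0.29, 3.84 ± 0.39 and 3.12 ± 0.35, and the dendritic cell genes Batf3 (-1.26 ± 0.21) and Xcr1 (-0.89 ± 0.22) fell.

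Neutrophil, B cell, red blood cell and interferon lists were not called. S100a8, a calprotectin subunit gene, was the 1 neutrophil marker of 13 that rose (3.83 ± 0.53), and the granule gene Camp (-1.88 ± 0.22), Mmp8 (-0.87 ± 0.29) and Trem1 (-0.72 ± 0.22) fell, the same counts adjusted over the list alone. The neutrophil median was 0.35 with the camera direction down (adjusted p = 0.780). Of 13 B and plasma cell markers 4 rose and 4 fell, also when adjusted over the list alone (median -0.16, mean 0.30, camera adjusted p = 0.851). The immunoglobulin joining chain gene Jchain rose by 3.82 ± 0.75, Cd79b by 1.77 ± 0.30 and Derl3 by 0.81 ± 0.23, and Fcrla (-1.33 ± 0.28), Fcer2a (-1.14 ± 0.37) and Pax5 (-0.77 ± 0.23) fell. Of 4 red blood cell genes Slc4a1 (-1.21 ± 0.28) and Epb42 (-0.96 ± 0.21) fell, 2 of 4 also when adjusted over the list alone (median -0.76, camera adjusted p = 0.208). Of 17 interferon response genes 6 rose and 1 fell, also when adjusted over the list alone (median 0.37, camera adjusted p = 0.644). Ddx58 rose by 1.62 ± 0.34, Xaf1 by 1.58 ± 0.35 and Ifih1 by 1.55 ± 0.26, and Rsad2 fell by 1.21 ± 0.25. Ddx58 had 2 further probe sets called the opposite way.

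Stromal lists were not called. Endothelial markers rose in 13 of 26 members and fell in 2, and adjusted over the list alone 11 rose and 2 fell (median 0.85, camera adjusted p = 0.183). The apelin receptor gene Aplnr rose by 3.74 ± 0.50, Gpihbp1 by 2.65 ± 0.34 and Plvap by 1.99 ± 0.26, and the angiopoietin receptor gene Tek (-2.06 ± 0.63) and Erg (-1.13 ± 0.30) fell. Of 20 fibroblast markers 4 rose and 3 fell, and adjusted over the list alone 3 rose and 3 fell (median 0.30, camera direction down, adjusted p = 0.964). Decorin (Dcn) rose by 3.73 ± 0.47, biglycan (Bgn) by 1.97 ± 0.41 and Col1a2 by 1.86 ± 0.46, and Dpt (-2.48 ± 0.69), Fbln1 (-2.45 ± 0.32) and Col13a1 (-1.37 ± 0.36) fell. Dcn and Col1a2 each had 1 further probe set called the opposite way, and the calls of Bgn and Col1a2 were lost after quantile renormalization (adjusted p = 0.190 and 0.232). Smooth muscle and pericyte markers rose in 6 of 14 and fell in 4, also when adjusted over the list alone (median 0.33, camera direction down, adjusted p = 0.964). The contractile genes Acta2 and Tagln rose by 3.90 ± 0.33 and 1.47 ± 0.23 and Notch3 by 1.57 ± 0.34, and Synpo2 (-2.11 ± 0.24), Cspg4 (-1.53 ± 0.27) and Myh11 (-1.15 ± 0.23) fell. Acta2 had 2 further probe sets called the opposite way, and with the mean of its probe sets its difference was 0.48 (adjusted p = 0.0655).

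Cardiac muscle markers, present where heart or large pulmonary vein tissue is sampled, fell in 3 of 10 members and rose in 0, also when adjusted over the list alone (median -0.04, camera adjusted p = 0.389). Ryr2 (-1.39 ± 0.29), Pln (-1.23 ± 0.35) and Mybpc3 (-0.56 ± 0.19) fell. Mesothelial markers rose in 2 of 9 and fell in 4, also when adjusted over the list alone (median -0.52, mean 0.01, camera adjusted p = 0.593). Keratin 19 (Krt19) rose by 4.54 ± 0.41 and mesothelin (Msln) by 2.35 ± 0.73, and Gpm6a (-2.83 ± 0.66), Lrrn4 (-1.79 ± 0.35) and Upk3b (-0.95 ± 0.29) fell. Genes of tumour progression and mesenchymal state fell in 7 of 15 and rose in 3, also when adjusted over the list alone (median -0.74, camera adjusted p = 0.239). Fibronectin (Fn1) rose by 2.36 ± 0.25, Lox by 2.03 ± 0.33 and periostin (Postn) by 1.66 ± 0.50, and the mesenchymal transcription factor gene Twist1 (-1.65 ± 0.22), Itga5 (-1.18 ± 0.23) and Igf2bp1 (-1.06 ± 0.21) fell. The call of Postn was lost after quantile renormalization (0.60, adjusted p = 0.387).

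Gastric and embryonic endoderm genes rose in 11 of 20 members and fell in 3, and adjusted over the list alone 12 rose and 3 fell. Gastrokine 2 (Gkn2) rose by 6.24 ± 0.52 (SE; limma adjusted p = 1.55e-08), from 5.63 ± 0.75 (SD, n = 8) to 11.87 ± 1.43 (SD, n = 7). The aspartic protease gene Ctse rose by 5.94 ± 0.52 and the tight junction gene Cldn4 by 3.42 ± 0.40, and Onecut2 (-1.61 ± 0.59), the intestinal regulator Cdx2 (-1.33 ± 0.24) and Gata4 (-1.03 ± 0.23) fell. Ctse had a second probe set called the opposite way, and the call of Onecut2 ended without tumour replicate 3 (adjusted p = 0.0519). The list's median was 1.61 (camera adjusted p = 0.133), at percentile 98.0 of random lists of the same tumour level (adjusted p = 0.147 over the 27 lists) and at percentile 99.3 of those of the same mean over all arrays (adjusted p = 0.0799).

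Cell cycle genes rose in 13 of 30 members and fell in 7, and adjusted over the list alone 13 rose and 6 fell (median 0.55, camera adjusted p = 0.816). Cyclin B2 (Ccnb2) rose by 2.48 ± 0.26, the replication clamp gene Pcna by 2.29 ± 0.37 and Cdk1 by 1.40 ± 0.27. The replication helicase gene Mcm3 (-3.84 ± 0.41), the thymidylate synthase gene Tyms (-2.43 ± 0.26) and Cdca8 (-1.35 ± 0.28) fell, and Mcm3 and Cdca8 each had 1 further probe set called the opposite way. Among normal arrays Mcm3 was lowest on replicate 3 (9.37), where the Actb and Gapdh controls were brightest (11.24). It was highest on replicate 2 (12.77), where they were weakest (7.33). Myod1, Dnaic1 and Fbln1, from other lists or tissues, were lowest and highest on the same arrays, and Tyms was not. Whether array signal accounts for these falls was not tested. The proliferation marker Mki67 differed by 0.96 ± 0.59 (limma adjusted p = 0.152), and without normal replicate 3 by 1.29 (adjusted p = 0.0380).

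Over the 27 lists, 9 were called with the preset correlation, 8 upward and 1 downward, and 0 with an estimated correlation, where 2 lists had an unadjusted p under 0.05. Against random lists of the same tumour level 0 of the 27 passed and 8 had an unadjusted p under 0.05 (smallest adjusted p = 0.0774, for ciliated, cardiac, and progression and mesenchymal genes). Against random lists of the same mean over all arrays 3 passed, namely alveolar type 2 markers and MAPK output genes upward and progression and mesenchymal genes downward (adjusted p = 0.0450 for the last). The called lists of macrophage, RAS, p53 and immediate early genes lay at percentiles 73.1, 7.66, 28.9 and 1.43 of the first kind of random lists and at 91.9, 23.5, 51.9 and 20.6 of the second. With dim genes left out the T and NK cell call remained and the 8 upward calls ended (adjusted p = 0.0555 to 0.498). The medians of these 8 lists were no smaller then, at 1.08 to 3.01 against 1.03 to 3.01 with all genes, while the median of all genes tested went from 0.13 to 1.17. After quantile renormalization the calls of macrophage, T and NK cell, RAS, p53 and immediate early genes ended (adjusted p = 0.0576 to 0.507), and with arrays scaled to the same SD those 5 and that of alveolar type 2 markers ended (adjusted p = 0.0510 to 0.369). With array weights the calls of macrophage, p53 and immediate early genes were lost (adjusted p = 0.0646 to 0.0947), and p53 targets also lost theirs with the mean of a gene's probe sets (adjusted p = 0.0746). Of 100 splits of the 15 arrays, the real one included, 45 gave 9 or more called lists. The drawn splits still held part of the difference between tumours and normal lung.

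**Figure D5:**
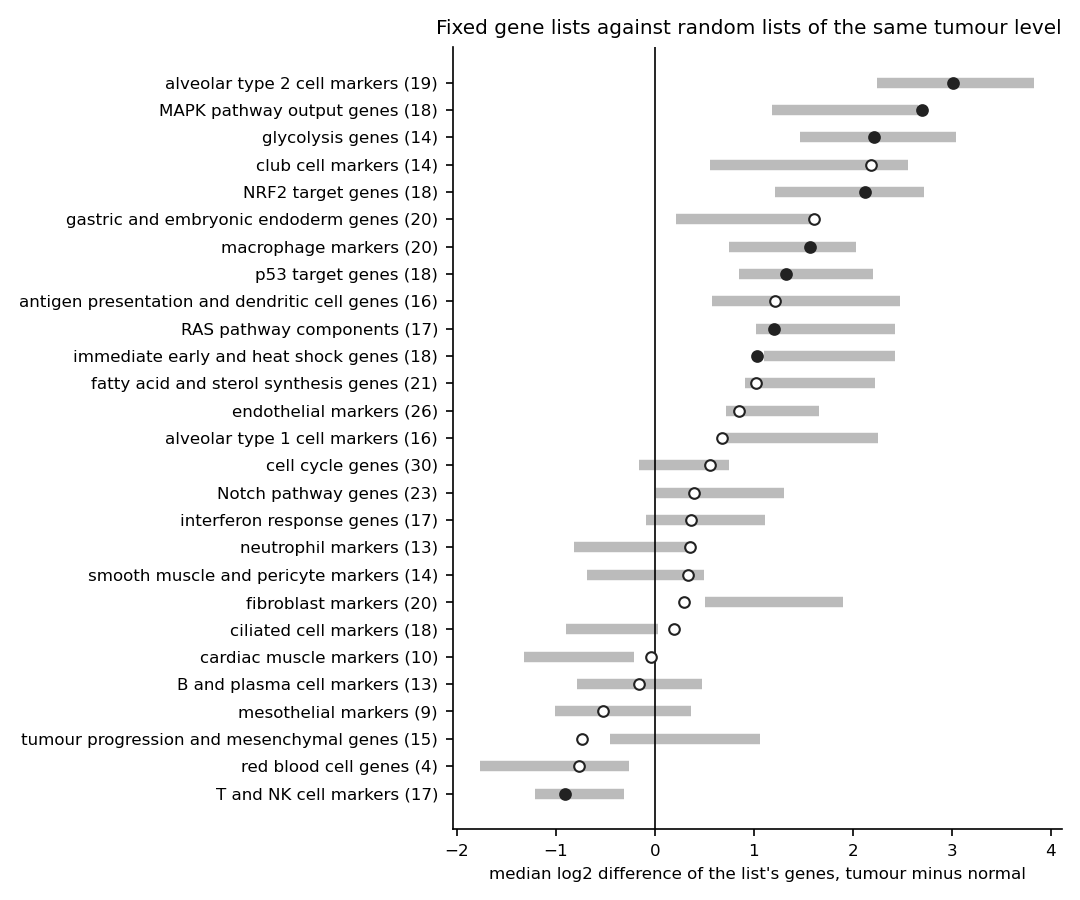
Median log2 difference (tumour minus normal) of each of 27 gene lists, with the number of measured genes in brackets; filled points were called by camera with the preset correlation. Grey bars hold the central 95% of medians of 10000 random lists of the same tumour level, and the alveolar type 2 median of 3.01 lay inside its bar.

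Tumours resembled one another more than normal lung samples did. The mean squared deviation of an array from the rest of its group was 0.214 ± 0.0746 (SD, n = 7) among tumours and 0.665 ± 0.267 (SD, n = 8) among normal arrays. The difference was -0.452 (permutation p = 0.000777, two-sided). That p-value is approximate, since the deviations were not computed again for each split. Pairs of tumour arrays correlated at r = 0.941 to 0.984 over all probe sets, and pairs of normal arrays at 0.451 to 0.850. Gkn2 (SD 1.43), Scgb1a1 (SD 1.54) and Jchain (SD 1.86) were among the named genes that varied between tumours. The Actb and Gapdh controls were weaker and more variable on the normal arrays.

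Sex-linked genes varied within both groups. Xist, transcribed from the inactive X chromosome, lay between 13.28 and 13.89 on tumour replicates 1, 2 and 3 and between 7.80 and 8.84 on replicates 4 to 7. The Y-linked gene Eif2s3y lay between 4.05 and 4.38 on the former and between 8.99 and 9.28 on the latter. Among normal arrays Xist ranged from 7.80 on replicate 8 to 13.22 on replicate 6. Eif2s3y lay between 4.05 and 5.54 on normal replicates 1 to 7 and at 6.93 on replicate 8, all below tumour replicates 4 to 7. The sexes may therefore not be balanced between the groups, although the weaker signal of the normal arrays leaves this uncertain. Between groups Xist differed by -0.78 ± 1.04 (limma adjusted p = 0.508), Eif2s3y by 1.99 ± 0.84 (adjusted p = 0.0416), Uty by 0.45 ± 0.70 (adjusted p = 0.576) and Kdm5d by -1.53 ± 0.26 (adjusted p = 4.91e-05). Kdm5d lay between 4.64 and 4.94 on tumour replicates 1 to 3 and between 4.87 and 5.06 on replicates 4 to 7. On normal arrays it lay between 5.32 and 7.29. Since it did not separate the tumours as Xist and Eif2s3y did, its fall cannot be read as a difference in sex. Eif2s3y had 1 further probe set called the opposite way, its call ended when any 1 of 10 arrays was left out (normal 2 to 7 or tumour 4 to 7; adjusted p at most 0.0972), and with the mean of its probe sets Kdm5d was not called (-0.57, adjusted p = 0.157).

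Further calls of named genes ended under another processing. After quantile renormalization these included Tagln, Ifih1, Cdkn2a, Epb42, Fcer2a, Fcrla, Gata4, Hey2, Mmp8, Mybpc3, Pax5, Pln and Xcr1, and all of these but Tagln and Ifih1 were also lost with arrays scaled to the same SD. With the mean of a gene's probe sets the calls lost included Cdca8, Xaf1, Upk3b, Ddx58, Peli1, Col1a2, Onecut2 and Pln. With the 3-prime minus 5-prime covariate they included Tek, Rtkn2, Col4a3, Spock2 and Eda2r, and with array weights Msln. Xist was called with arrays scaled to the same SD.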

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

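Tests of the signal of the arrays, of their value distributions, of the MAPK list and of Sftpc were chosen after the results were seen, and the Sftpc correlation test was chosen after an earlier test had decided nothing; the counts over splits of the samples were planned. Of 378 groups of arrays examined for a single array far from the rest, 36 had one, where chance gives about 1 in 20, or 18.9. Normal replicate 3, which had the brightest Actb and Gapdh controls of the normal arrays (11.24), accounted for 15 of the 36.

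On normal replicate 3, Rplp2 lay at 9.17 (other normal arrays 4.67 to 6.80), Atp5b at 8.51, P4hb at 9.44, Cd74 at 11.25, H2-Ab1 at 11.50, Aldoa at 10.06 and the mean of cardiac muscle markers at 7.86 (others 5.20 to 6.00), each above every other normal array. On the same array Synpo2l lay at 10.09 (others 12.63 to 13.63), Myod1 at 4.92, Opa3 at 7.62, Serpina7 at 7.91, Peli1 at 8.68, Lrrn4 at 5.78, Mcm3 at 9.37 and the hybridization controls at 13.41, each below the others. Normal replicate 2 had Ccnd1 at 6.97, Sftpc at 8.63 and the lowest mean correlation with its group, 0.594. Upk3a lay at 6.90 on normal replicate 8, Upk3b at 7.65 on normal replicate 1 and Notch1 at 6.92 on normal replicate 6. B and plasma cell markers averaged 6.18 on normal replicate 7 and cell cycle genes 6.58 on normal replicate 5, each below the other normal arrays.

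Among tumours, replicate 5 stood apart in Krt15 (5.50), Dnah5 (6.90), Pln (6.13) and Me1 (10.36, below the others). Tumour replicate 6 had Plvap at 10.25, alveolar type 2 markers at 13.03 and immediate early and heat shock genes at 10.15, each above the other tumours. Tumour replicate 1 had Ryr2 at 4.47, Map2k1 at 10.85 and Gsta4 at 13.42. Notch1 lay at 9.15 and the hybridization controls at 10.47 on tumour replicate 2, both below the others, and Gata4 at 5.49 on tumour replicate 3. The poly-A Dap controls, which are bacterial RNA and enter no comparison of tissue, averaged 8.21 on tumour arrays and 4.12 to 5.59 on single normal arrays.

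Most genes differed between tumours and normal lung. Chance is argued against for the number of genes, since 1 of 100 splits of the arrays, the real one, gave as many and the highest of the others gave 8988. That count cannot go below 1 of 100, and it takes the arrays as independent although the animal of each is not given. A difference in value distribution alone is argued against by 8396 calls that stayed in the same direction after quantile renormalization. After it the Actb and Gapdh controls still differed by 3.03 and the hybridization controls by -4.19 (tumour minus normal). The calls that stayed therefore cannot separate tissue from array signal. Weaker sample signal on the normal arrays stays open and may contribute, since the hybridization controls were 3.47 brighter there. Across the normal arrays 61.95% of the changed genes moved toward the tumour level as the Actb and Gapdh controls brightened (one-sided exact permutation p = 0.0941 over 40320 orders), and 55.0% without normal replicate 3, so a trend of signal could not be decided. Tissue and array signal cannot be told apart, and a difference in the strand or region labelled, which was not tested, and the biological difference that the design names stay open as well.

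The calls of gene lists with the preset correlation are open to chance. Of 100 splits, 45 gave at least the 9 lists of the real split, with 21 in the highest of the others. The drawn splits put 1 to 6 tumours on the same side, so part of the difference between tumours and normal lung stayed in them. The count is therefore not a pure measure of chance and cannot decide the question, and why so many lists were called was not tested. MAPK output genes lay at percentile 98.03 of random lists of the same tumour level, so a rise shared by all genes of that level could not be decided for them. Against random lists of the same mean over all arrays 3 lists passed, so the answer depends on the reference. A rise of MAPK output in these tumours could be real, but no test here separates it from the signal of the arrays.

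The 2 probe sets of Sftpc disagreed in tumours. On the 8 normal arrays they followed one another (Pearson r = 0.984, exact permutation p = 4.96e-05, and Spearman rho = 0.976, exact permutation p = 0.000397). Without the 2 arrays farthest from the median Pearson r was 0.944. The second set lay at percentile 99.99 of all probe sets in that correlation, as it would if both measured Sftpc there. The first set also followed the Actb and Gapdh controls over these arrays (r = 0.884), so array signal may contribute to that agreement. From normal to tumour arrays the second set's mean went from 11.99 to 4.28 while the first, at the top of the scale on tumour arrays, was higher there. That argues against both sets measuring the same RNA in the same way. Their difference moved by -10.81, which may be inexact if the first set was limited there. The test first tried, the percentile of the second set's tumour level among all probe sets (14.4), had decided nothing. A difference between the groups in labelling or in the strand or region measured may explain this, but probe sequences were not used here and no biological explanation was tested.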

How the results depend on the processing

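Scaling to the same SD, both kinds of matched lists, the spread without its factor and the joint removal of 2 arrays were chosen after the results were seen. Of 4272 values of named genes under other settings 4121 kept their side of the threshold, with any change of sign only where neither setting had a call. A further 141 lost the call, 7 gained it and 3 reversed. Reversed here means a change of sign with a call in at least 1 of the compared settings. Of 862 values of lists these were 785, 67, 4 and 6. The call held in every setting in which it was tested for 109 of 154 named genes and 16 of 27 lists. With dim genes left out, 114 named genes and not all lists were tested. The number of changed genes was 12790 (without tumour replicate 4) to 13511 (without normal replicate 3) with 1 array left out, that of lists 7 to 10, and the difference in spread -0.506 to -0.380. Without dim genes 8072 of 10916 genes were called, and 31948 of 45101 probe sets, as fewer genes or more probe sets were tested. Without dim genes 1 list was called, while the median of all genes tested went from 0.13 to 1.17 and those of the 8 lost lists did not fall. The dim genes left out had a median of -0.84. Camera tests each list against all other genes, so this higher reference works against upward calls. How much of each lost call it accounts for was not tested. Lists numbered 4 after quantile renormalization, 3 with the same SD, 0 with an estimated correlation, 0 against random lists of the same tumour level and 3 against those of the same mean; the cause was not tested.

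With the mean of probe sets, Peli1 (0.32), Ddx58 (-0.36) and Sftpc (-2.30) reversed in sign, since their probe sets disagree, and Peli1 was no longer called (limma adjusted p = 0.278). Relative to random lists of the same tumour level the medians of RAS components (-0.55), glycolysis (-0.0931), p53 targets (-0.20) and immediate early genes (-0.73) reversed, and relative to lists of the same mean those of RAS components (-0.31) and immediate early genes (-0.35); the cause was not tested. With a replicate block 12706 genes and 7 lists were called, against 13011 and 7 on the same arrays without it. Same-numbered arrays correlated at -0.0304 to 0.0935, and 2 of 7 tumours correlated best with their own number. These values gave no clear sign that the numbers pair the samples. They cannot exclude it, since signal varied between the normal arrays. Without its factor the difference in spread was -0.511. RMA values show no background, so what dim genes can show is limited.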

Other observations

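Tumours differed among themselves in markers of many cell types; these patterns were noticed after the values were seen and no test was run on them. Tumour replicates 5 and 6, which had the brightest poly-A controls (9.06 and 8.98), had ciliated cell markers at 8.12 and 7.38, against 5.40 to 5.81 on the other 5, and the ciliary regulator Foxj1 at 8.64 and 8.23, against 4.93 to 5.28. Fibroblast markers averaged 9.92 and 9.66 on these tumours and 8.06 to 8.31 on the others, endothelial markers 9.26 and 9.71 against 7.60 to 8.09, alveolar type 1 markers 9.99 and 10.60 against 8.66 to 9.19, and cardiac muscle markers 7.40 and 6.48 against 4.88 to 5.26. Immune lists stood apart too, with neutrophil markers at 8.24 and 7.21 against 5.61 to 6.81, B and plasma cell markers at 8.47 and 7.33 against 6.30 to 7.28, macrophage markers at 9.73 and 9.23 against 8.41 to 8.86 and T and NK cell markers at 6.20 and 6.25 against 5.22 to 5.78. Of the 27 lists 18 lay above the other 5 tumours on both of these and 1 lay below, namely the cell cycle genes. They averaged 6.88 and 7.01 there and 7.13 to 7.79 on the others.

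Tumour replicate 1 carried secretory and protease genes that the other tumours had at lower levels. Tff1, a trefoil peptide gene of gastric mucosa, lay at 14.80 (8.34 to 9.68 on the other tumours), Tff2 at 12.71 (6.23 to 8.55), Lgals4 at 12.63 (7.43 to 9.61), Dmbt1 at 11.43 (4.10 to 7.30) and the intestinal phosphatase gene Alpi at 11.90 (5.22 to 5.95). The mast cell and basophil protease genes Mcpt2 and Mcpt8 lay at 14.05 (5.62 to 9.86) and 12.56 (4.68 to 8.73). Mcpt1 lay at 9.56 (3.61 to 5.37) and the mast cell tryptase gene Tpsab1, outside the marker list, at 10.38 (5.07 to 6.21), while the mast cell genes Cpa3 (3.92), Tpsb2 (4.99) and Fcer1a (3.70) were no higher than on other tumours. Of 12 mast cell and basophil markers 3, and of 18 gastric and intestinal secretory markers 4, exceeded every other tumour by more than 1 on the log2 scale. Between tumours and normal lung these lists, written after the values were seen, had 2 higher and 6 lower genes (median -0.49) and 6 higher and 4 lower genes (median 0.66). Genes that exceeded every other tumour by more than 2 numbered 40 on tumour replicate 1 and 45 on replicate 5, and 1 to 12 on the others.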
